A study of Mus musculus with 6 samples.

How the data were processed

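RNA sequencing of mouse mammary gland was analysed in 6 samples. All came from C57BL/6 mice at postnatal day 45: 3 untreated samples and 3 samples given recombinant mouse CXCL14 protein, numbered 1 to 3 in each group per the labels. Per the labels' protocol, glands were frozen on dry ice, RNA was extracted with Trizol, and 2 µg of RNA per sample went into libraries made with an NEBNext Ultra RNA kit. Per the series' design text, an Illumina HiSeq instrument was used. Whether reads were counted by strand is not given in the sources used here. The series title speaks of endothelial cells, while the sample labels give mammary gland as the tissue. The dose, route and duration of the treatment are not given in the sources used here, nor is a batch. Nothing says that the samples of a group came from separate animals, so p-values measure the spread between these samples, which may be partly technical.

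The authors deposited one FPKM value per gene symbol and library, for 17464 symbols in each library. FPKM is a fragment count divided by the gene's length and by the library's total, a unit already scaled for both. The submitters' processing notes name Bowtie2 2.2.3, HISAT2 2, HTSeq 0.6.0 and the genome build mm8, with no role or order. Gene lengths, annotation and filters on genes are not given in the sources used here. Of the symbols, 16849 matched a GENCODE M21 name table and 17350 a RefSeq table of GRCm38.p6, while 109 matched neither. Because that assembly is not the one the submitters name, no coordinates are given. Symbols were used as deposited. Whether reads shared by near-identical genes, overlapping genes or antisense genes were split is not known, so values of such families are uncertain.

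The deposited FPKM values keep the steps of whole reads. Within a gene, values were whole multiples of one step per library, which gave read numbers up to a common factor for 17437 of 17464 genes (99.8%) within a tolerance of 0.004 reads, and for all 11516 genes tested. These recovered reads came to between 15245954 and 16983249 per library. They served for depth, for comparing libraries with counting noise, and for one alternative test, and never for the main result.

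The design, the gene lists, the rule for naming genes and the first set of alternative settings were fixed before the data were examined. Count-based testing had been foreseen for count tables, with limma-trend for FPKM, so limma-trend was used. Genes with an FPKM of at least 1 in at least 3 libraries were kept. Values were taken as log2(FPKM + 1), so a fold change is on that scale and understates the change of low genes. The fit used limma 3.58.1 in R 4.3.3, with moderated variances that follow a trend with expression, and the Benjamini-Hochberg adjustment over all 11516 genes. A gene was called at an adjusted p under 0.05. Standard errors are the moderated ones, and SDs are over the libraries of a group.

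Of 43 gene lists of cell types, pathways and quality signs, 36 had at least 5 tested members. These were tested with camera, which compares a list with all other genes, at a preset inter-gene correlation of 0.01, run on log2(FPKM + 1) rather than on the voom values foreseen for counts. Lists were adjusted over the 36. Camera with an estimated correlation and fry, which asks whether a list's genes move one way on balance, were alternatives. Members were counted after adjustment over all genes, and again adjusted over the list alone.

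Genes were named by a fixed rule. Cxcl14 and Cxcr4 were always named. Called genes with a mean of at least 1 (FPKM here, CPM in the rule), non-overlapping groups and a symbol that is not a predicted or clone name were to be named, the 12 with the highest and the 12 with the lowest fold change. Where fewer passed, the genes with the smallest unadjusted p under the same other conditions filled the places and are said not to pass. Up to 4 members with the smallest p were named for each list called by camera or holding at least 2 called members. The 2 members with the smallest p were named for blood endothelium, angiogenic genes, luminal epithelium, basal and myoepithelial cells, macrophages and chemokine ligands. Applying the rule again without CXCL14 replicate 1, and any gene named outside the rule, was a choice made after the values were seen.

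The same code was tested on simulated data with 200 of 11516 genes altered, in 5 rounds. For 3 against 3 libraries it found 99.2% of 2-fold changes at a replicate CV of 10%, and 18.0% at a CV of 30%, where it found 95.6% of 4-fold changes. For 3 untreated against 2 CXCL14 libraries it found 97.6% of 2-fold changes at a CV of 10%, and 10.8% at a CV of 30%, with 88.0% of 4-fold changes. False calls made up between 2.22% and 7.46% of calls. Noise was drawn for each gene on its own at a single CV, without the differences shared by many genes that the real libraries hold. These rates therefore do not say what share of real changes would be found here.

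Alternatives were voom on the recovered reads with TMM scaling (written out for this work), median-ratio and upper-quartile scaling, no filter, a CPM filter, the replicate number as a block, each library left out in turn, and the 20 most abundant genes left out. Added after seeing the data were a pseudocount of 0.1, quantile normalization, robust variance estimation, leaving out both libraries numbered 1, and 3 settings combined with leaving out CXCL14 replicate 1. Mitochondrially encoded and sex-linked genes were not analysed here.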

Results

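Gene expression was measured in the mammary gland of C57BL/6 mice at postnatal day 45. The comparison was between 3 untreated samples and 3 samples given recombinant mouse CXCL14, a chemokine. The series title gives endothelial transcriptomes in the mammary gland as the subject, so endothelial and angiogenic genes are described first among the gene groups. Between 15245954 and 16983249 reads were recovered per library, and between 11030 and 11652 genes reached an FPKM of at least 1.

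The tissue was rich in lymphoid transcripts in each of the 6 libraries, and the labels do not say whether the glands held a lymph node or whether cells were sorted. The median FPKM over 13 B-cell markers was between 66.7 and 91.9, and over 8 genes of MHC class II presentation between 501 and 654. Markers of lymph node stroma and high endothelial venules, 5 genes, had a median between 1.78 and 6.37. Blood endothelial markers had a median between 25.2 and 85.1, luminal epithelial markers between 6.85 and 16.0, and white adipocyte markers between 4.18 and 11.2. Immediate early genes, which respond within minutes to many stimuli, had a median between 233 and 348.

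Chka, a choline kinase, and Slc7a5, an amino acid transporter, were higher in all 3 CXCL14 libraries than in all 3 untreated libraries, and Pglyrp2, which cleaves peptidoglycan, was lower, but none of the 3 passed the test. Chka measured 18.2 ± 4.42 FPKM with CXCL14 and 9.82 ± 0.220 without (SD, n = 3 each), a log2 fold change of 0.80 with SE 0.17. Slc7a5 had a log2 fold change of 0.55 (SE 0.12), and Pglyrp2 one of -0.80 (SE 0.21). The other genes with the smallest p on the higher side were Sprr1a, Rilpl2, Mcrip2, Rab4a, Cdc20, Vps18, H4f16, Tfip11, Tnfrsf12a and Ddit3, with log2 fold changes between 0.46 and 0.92. On the lower side they were Nutf2, Ecsit, Dand5, Ifi208, Mff, Ifi214, Blvra, Borcs8, Akr1c13, Abhd8 and Fam136a, between -0.65 and -0.33. Limma-trend called none of the 11516 genes, 0 higher and 0 lower, with a smallest adjusted p of 0.573 and 895 genes at an unadjusted p under 0.05 (7.77%). Voom on the recovered reads also called 0, with 752 genes at that unadjusted p. Groups did not overlap for 1509 genes (13.1%, against 10% by chance).

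The count of 0 depended on a single library. With CXCL14 replicate 1 left out, limma-trend called 249 genes higher and 348 lower, and groups did not overlap for 5568 genes (48.4%, against 20% by chance). With both libraries numbered 1 left out, it called 14 higher and 1 lower. Of the 597 genes called without CXCL14 replicate 1, all 597 had the same direction with all 6 libraries, with a median ratio of log2 changes of 0.702 (all 6 libraries to 5). The 5 libraries are part of the 6, so the shared direction and smaller change largely follow by construction and are no separate check. In that fit the median log2 fold change over all genes was -0.10 and 41.7% of the calls were higher. Median-ratio scaling moved this median to 0.01 and the calls to 321 higher and 117 lower, 73.3% higher, and voom gave 171 and 62, 73.4% higher.

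CXCL14 replicate 1 lay next to untreated replicate 1. On the recovered reads their mean chi-square per gene was 2.24, where counting noise alone gives 1, while the other 14 pairs of libraries lay between 22.9 and 84.8. Both were kept as labelled, since the pair differed by more than sampling noise and its libraries belong to different groups. That difference argues only against 1 library under both labels, as far as sequencing adds counting noise alone. Libraries made from the same RNA or tissue sample could also differ by more than sampling noise. The comparison of all 6 libraries therefore rests on the label of CXCL14 replicate 1. The first principal component held 61.1% of the variance. Untreated replicates 1, 2 and 3 had scores of 27.2, 8.94 and 2.30 on it, and CXCL14 replicates 1, 2 and 3 had scores of 24.1, -28.4 and -34.2. Values without CXCL14 replicate 1 are given beside those of all 6 libraries for the gene groups described, as counts of calls and, for part of the groups, as medians. Leaving out a treated library that resembles a control widens the difference between groups by construction, so these values are not independent evidence of an effect, and genes named for their calls in that fit were chosen after their values were seen.

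**Figure D1:**
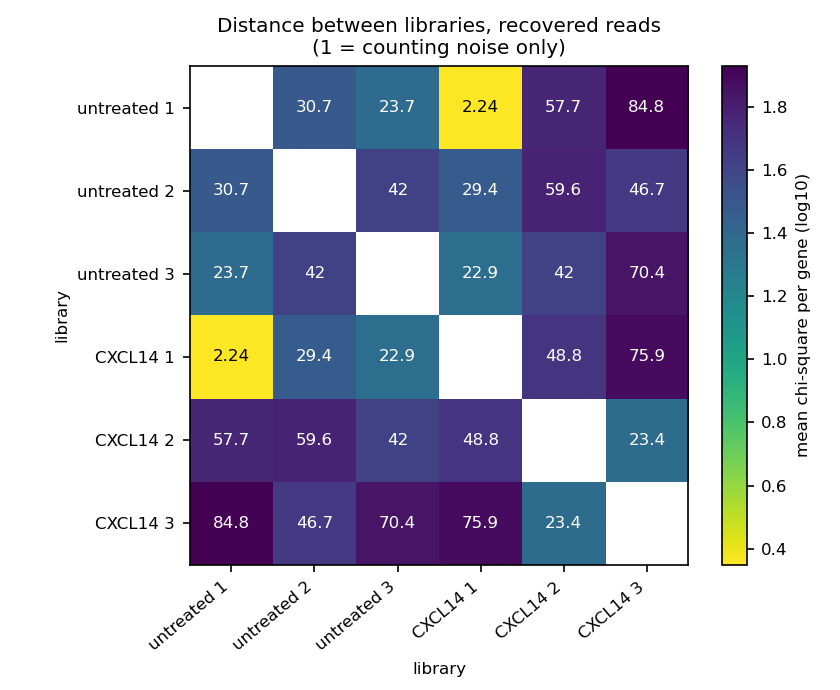
Mean chi-square per gene between each pair of the 6 libraries, from recovered reads, with both axes listing the libraries and colour on a log10 scale. Untreated 1 and CXCL14 1 differ by 2.24, and the other 14 pairs by 22.9 to 84.8.

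The transcript of Cxcl14 itself was low and did not pass the test. It measured 2.61, 0.934 and 0.214 FPKM in untreated replicates 1, 2 and 3, and 2.27, 2.14 and 2.75 FPKM in CXCL14 replicates 1, 2 and 3, a log2 fold change of 0.73 (SE 0.37, limma-trend adjusted p = 0.574). Protein given from outside does not add this transcript. Cxcr4, a chemokine receptor, measured 331 ± 55.3 FPKM with CXCL14 and 255 ± 31.0 without (SD, n = 3 each), a log2 fold change of 0.37 (SE 0.16, limma-trend adjusted p = 0.573). Of 26 chemokine ligands tested 0 passed, over all genes and adjusted over the list alone, and the same held for 15 chemokine receptors. Ccl22, a dendritic cell chemokine, was at 59.4, 56.2 and 36.6 FPKM in the untreated libraries and at 59.6, 6.39 and 9.65 FPKM in CXCL14 replicates 1, 2 and 3. With CXCL14 replicate 1 left out, 3 of the 26 ligands fell, with log2 fold changes of -2.51 for Ccl22 (limma-trend adjusted p = 0.0251), -1.07 for Cxcl16 and -0.95 for Ccl17, and 3 fell adjusted over the list alone. Of the 15 receptors 2 then rose, among them Cxcr5 with a log2 fold change of 0.61, and 1 fell, Ccr9 with -1.25. Adjusted over the list alone, 4 receptors rose and 1 fell. The median log2 fold change was -0.22 for the ligands and -0.22 for the receptors with all libraries, and -0.54 and -0.41 without CXCL14 replicate 1.

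All 20 blood endothelial markers had a positive log2 fold change, with a median of 0.27, and 0 of them passed over all genes or adjusted over the list alone. Vwf, which carries a clotting factor in the blood, measured 44.8 ± 28.3 FPKM with CXCL14 and 21.7 ± 13.6 without (SD, n = 3 each), a log2 fold change of 0.92 with SE 0.61. Plvap, a diaphragm protein of fenestrated vessels, had 0.67 (SE 0.51), Sox17 0.45 (SE 0.45) and Cd34 0.24 (SE 0.24). The median FPKM over the list was 25.2, 54.7 and 44.2 in untreated replicates 1, 2 and 3 and 26.7, 50.3 and 85.1 in CXCL14 replicates 1, 2 and 3. Camera called the list up (adjusted p = 0.00198), a call that was lost with an estimated correlation (adjusted p = 0.864 with an estimated correlation). Of 22 angiogenic ligands, receptors and tip-cell genes, 13 had a positive fold change and 0 passed over all genes or adjusted over the list alone. Vegfa, a vascular growth factor, measured 10.8 ± 1.88 FPKM with CXCL14 and 6.12 ± 1.34 without (SD, n = 3 each), a log2 fold change of 0.73 (SE 0.18, limma-trend adjusted p = 0.573), with all 3 CXCL14 libraries above all 3 untreated. Apln and Pgf had log2 fold changes of -0.56 and -0.41. Camera called this list up (adjusted p = 0.0277, and adjusted p = 0.864 with an estimated correlation). In the fit without CXCL14 replicate 1, Vegfa alone of the 22 rose (log2 fold change 0.87, limma-trend adjusted p = 0.0495), with 0 of the 22 passing adjusted over the list alone, and 0 of the 20 endothelial markers passed either way. In that fit log2 fold changes were 1.54 for Vwf, 1.18 for Plvap, 0.93 for Sox17 and 0.35 for Cd34. The median was 0.65 for the endothelial list and 0.38 for the angiogenic list. Without both libraries numbered 1 these medians were 0.39 and 0.21.

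White adipocyte and pericyte markers were, like endothelial markers, lowest in untreated replicate 1 and CXCL14 replicate 1. The mean log2(FPKM + 1) over 15 white adipocyte markers was 2.97, 3.66 and 3.58 in untreated replicates 1, 2 and 3 and 3.01, 3.39 and 4.32 in CXCL14 replicates 1, 2 and 3. Of the 15, 13 had a positive log2 fold change, with a median of 0.17, and the list was not called (camera adjusted p = 0.0635). Without CXCL14 replicate 1, 14 were positive, with a median of 0.48, and the list was called up (adjusted p = 0.00200, and adjusted p = 0.650 with an estimated correlation). Of 8 pericyte markers 5 were positive with all libraries and 8 without CXCL14 replicate 1, with medians of 0.01 and 0.37 and no call of the list. Without both libraries numbered 1, the adipocyte median was 0.27 and the pericyte median 0.05, with 6 of 8 pericyte markers positive. For both lists 0 members passed over all genes or adjusted over the list alone, in either fit.

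Genes of milk secretion were high in CXCL14 replicates 2 and 3 and low in the other libraries. Csn2, which encodes beta-casein, was at 0.772, 1.26 and 1.63 FPKM in the untreated libraries and at 1.13, 171 and 271 FPKM in CXCL14 replicates 1, 2 and 3. Lalba, which encodes alpha-lactalbumin, was at 0.549, 0.730 and 1.04 FPKM and at 1.12, 23.9 and 29.3 FPKM in the same order. All 6 tested members of the list had positive log2 fold changes, with a median of 2.54, and 0 passed over all genes or adjusted over the list alone. Wfdc18 had a log2 fold change of 2.36 (SE 0.77) and Btn1a1, a protein of milk fat globules, one of 1.35 (SE 0.54). Camera called the list up (adjusted p = 5.20e-06, and adjusted p = 0.520 with an estimated correlation). With CXCL14 replicate 1 left out, 5 of the 6 rose, among them Csn2 with a log2 fold change of 6.62 (limma-trend adjusted p = 0.00373), Csn3 with 4.12 and Lalba with 3.96, and 6 rose adjusted over the list alone.

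The 17 luminal epithelial markers had a median log2 fold change of -0.02, and 0 passed over all genes or adjusted over the list alone. Their mean was 0.08 and camera's direction was up, without a call (adjusted p = 0.139). Elf5, a transcription factor of the secretory lineage, was at 1.05, 1.89 and 0.819 FPKM in the untreated libraries and at 1.15, 4.80 and 7.63 FPKM in CXCL14 replicates 1, 2 and 3. Elf5 was the 1 luminal marker of 17 that rose without CXCL14 replicate 1 (log2 fold change 1.68, limma-trend adjusted p = 0.0413), and 1 rose adjusted over the list alone. Cldn7, a tight junction protein, had a log2 fold change of 0.46 (SE 0.18) with all libraries. Of 5 basal and myoepithelial markers 0 passed over all genes or adjusted over the list alone, in either fit, with all-library log2 fold changes of 0.55 (SE 0.31) for Krt14 and 0.42 (SE 0.57) for Tagln. The basal list had 3 of 5 positive and a median of 0.06 with all libraries, 5 of 5 and 0.48 without CXCL14 replicate 1, where Tagln had 0.95, and 3 of 5 and 0.06 without both libraries numbered 1.

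**Figure D2:**
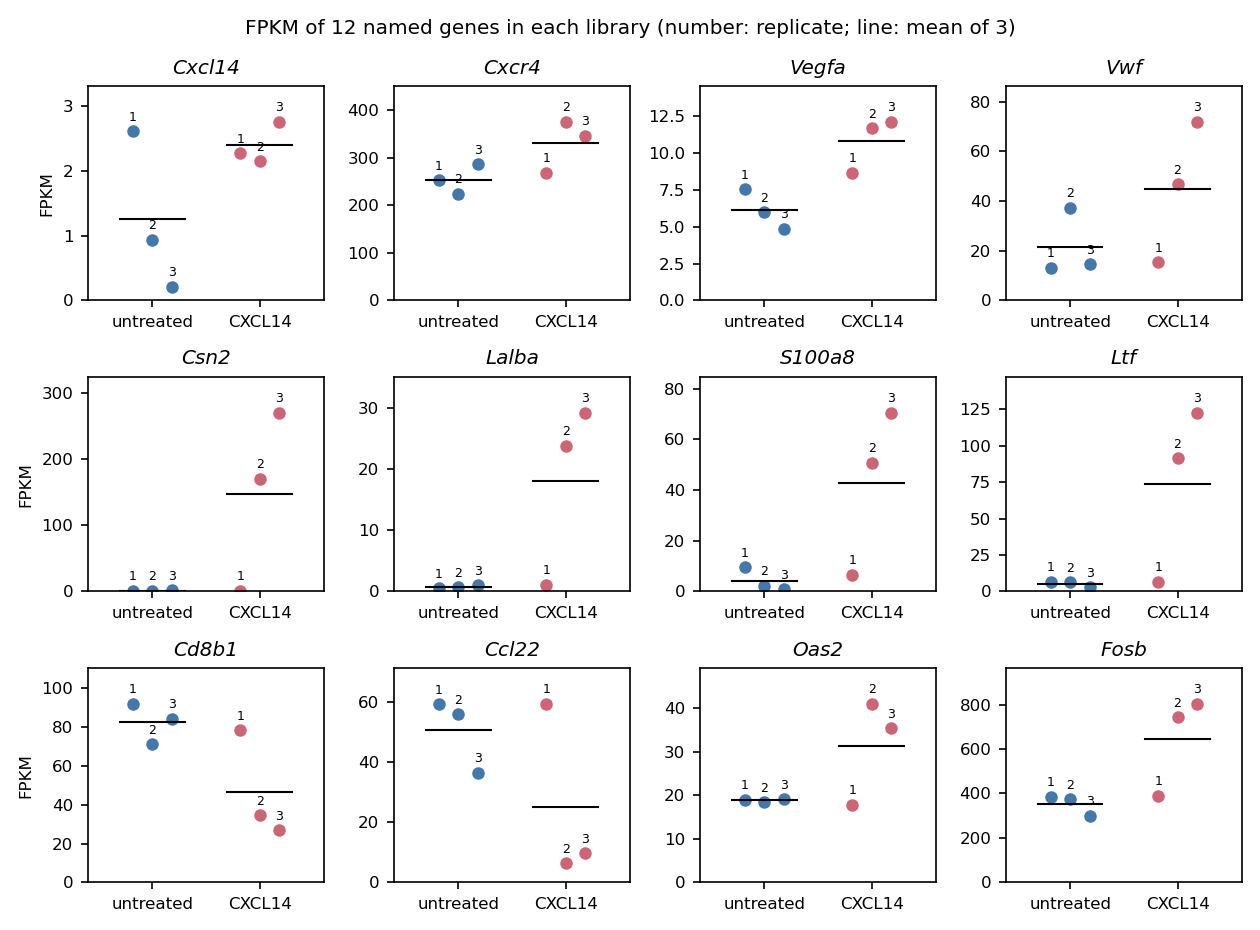
FPKM (vertical axes, linear from 0) of 12 named genes in each library, with points numbered by replicate and a line at each group's mean of 3. For Csn2, CXCL14 replicates 2 and 3 lie at 171 and 271 and replicate 1 at 1.13.

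Neutrophil genes were also highest in CXCL14 replicates 2 and 3. S100a8, a calcium-binding protein abundant in neutrophils, was at 9.63, 2.33 and 0.763 FPKM in the untreated libraries and at 6.55, 50.7 and 70.5 FPKM in CXCL14 replicates 1, 2 and 3. The 8 tested members all had positive log2 fold changes, with a median of 2.19. Over all genes 0 passed, and 6 rose adjusted over the list alone. Retnlg had a log2 fold change of 2.28 (SE 0.69), Camp, an antimicrobial peptide, 1.64 (SE 0.47) and Ngp 2.09 (SE 0.69). Camera called the list up (adjusted p = 4.61e-08, and adjusted p = 0.520 with an estimated correlation). With CXCL14 replicate 1 left out, 5 of the 8 rose over all genes and 6 adjusted over the list alone, with log2 fold changes of 4.16 for Ltf, which mammary epithelium also makes, and 3.72 for S100a9. All 4 red blood cell genes tested, too few for a test of the list, were also positive, with a median of 0.52, and with 1.13 without CXCL14 replicate 1. Of these 4, 0 passed over all genes in either fit, and adjusted over the list alone 0 passed with all libraries and 3 rose without CXCL14 replicate 1.

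T-cell genes were lower in CXCL14 replicates 2 and 3. Cd8b1, a chain of the CD8 co-receptor, was at 92.0, 71.2 and 84.2 FPKM in the untreated libraries and at 78.4, 34.6 and 27.0 FPKM in CXCL14 replicates 1, 2 and 3. The 17 T and NK markers had a median log2 fold change of -0.39, with 12 negative and 0 passing over all genes or adjusted over the list alone. Cd4 had a log2 fold change of -0.51 (SE 0.17), Cd3e of -0.53 (SE 0.21) and Cd247 of -0.50 (SE 0.16). Camera called the list down (adjusted p = 0.0207, and adjusted p = 0.864 with an estimated correlation). In the fit without CXCL14 replicate 1, 6 of the 17 fell over all genes and 11 adjusted over the list alone, with log2 fold changes of -1.40 for Cd8b1 and -0.78 for Cd3e and a median of -0.63 over the list.

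Of 7 dendritic cell markers 0 passed with all libraries, and their median log2 fold change was -0.71, or -1.18 without CXCL14 replicate 1. With CXCL14 replicate 1 left out 3 fell, with log2 fold changes of -1.87 for Cd209a, -1.18 for Flt3 and -1.26 for Itgax, and 1 rose and 5 fell adjusted over the list alone. B-cell markers had a median log2 fold change of -0.09, beside -0.06 over all genes. Over all genes 0 of the 13 B-cell markers passed in either fit, and adjusted over the list alone 0 passed with all libraries and 1 rose and 3 fell without CXCL14 replicate 1. Of 15 macrophage markers, with a median of -0.77, 0 passed over all genes or adjusted over the list alone, in either fit. Cd14, an endotoxin co-receptor, had a log2 fold change of 1.21 (SE 0.45) and C1qa, a complement component, one of -1.21 (SE 0.88). Without CXCL14 replicate 1 the macrophage median was -1.49, and C1qa had -2.21 without passing. Macrophage markers differed within groups, with a median FPKM of 26.9, 22.3 and 4.77 in untreated replicates 1, 2 and 3. In CXCL14 replicates 1, 2 and 3 it was 25.4, 3.03 and 4.08, so untreated replicate 3 lay near CXCL14 replicates 2 and 3. Of 3 plasma cell genes, too few for a test of the list, 0 passed over all genes and 2 rose adjusted over the list alone, in either fit.

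Lists of interferon, inflammatory, stress and cell cycle genes were called up by camera, while 0 of their members passed over all genes or adjusted over the list alone. Of 21 interferon response genes 20 had positive log2 fold changes, with a median of 0.44, as in Irf7 (0.51, SE 0.27) and Oas2 (0.63, SE 0.29). The list's adjusted p was 9.67e-07, and adjusted p = 0.738 with an estimated correlation. Of 21 NF-kB and acute inflammation genes 18 were positive, with a median of 0.41, as in Nfkbia (0.55, SE 0.22) and Tnf (0.63, SE 0.22). All 19 immediate early genes were positive, with a median of 0.27, as in the transcription factor genes Fosb (0.81, SE 0.28) and Klf4 (0.67, SE 0.21). Of 18 heat shock and unfolded protein response genes 15 were positive, with a median of 0.23, as in Ddit3 (0.62, SE 0.15) and Xbp1 (0.42, SE 0.15). Of 25 cell cycle genes 22 were positive, with a median of 0.25, as in Top2a (0.51, SE 0.14) and Foxm1 (0.47, SE 0.14). The last 4 lists had adjusted p = 1.84e-07, 2.94e-09, 2.90e-06 and 1.84e-07 in this order, and each had adjusted p = 0.520 with an estimated correlation. With CXCL14 replicate 1 left out, 6 of 21 interferon genes rose over all genes and 16 adjusted over the list alone, with a median of 0.74. Irf7 and Oas2 were among the 6, with log2 fold changes of 0.83 and 0.98 (limma-trend adjusted p = 0.0268 and 0.0236). In the same fit 3 of 21 NF-kB genes rose, against 8 that rose and 1 that fell adjusted over the list alone, and 5 of 19 immediate early genes rose, against 8. Of the heat shock and unfolded protein response genes 1 of 18 rose, against 5 adjusted over the list alone, and of the cell cycle genes 1 of 25, against 2.

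Metabolic and clock-related lists had members that went both ways. Ciart and Per1, genes of the circadian clock, had log2 fold changes of 0.72 and 0.37 and Dbp one of -0.72. The glucose transporter gene Slc2a1 had 0.53 and Pfkl, a glycolytic enzyme, 0.43, while Pdk1 and Eno1 had -0.71 and -0.39. Lcn2, which binds iron carriers of bacteria, had 2.27 (SE 1.02), and Dgat1, an enzyme of triglyceride synthesis, 0.55 (SE 0.20). Without CXCL14 replicate 1, Lcn2 had 3.52 (limma-trend adjusted p = 0.0268) and Dgat1 0.55 without passing. Camera called up the glucocorticoid response, circadian clock, hypoxia and glycolysis, and fatty acid and triglyceride synthesis lists, with adjusted p = 0.00227, 0.00669, 0.0218 and 0.0122. In this order they had adjusted p = 0.520, 0.711, 0.583 and 0.738 with an estimated correlation. Nuclear-encoded respiratory chain subunits were called down (adjusted p = 0.0218, and adjusted p = 0.864 with an estimated correlation). Of these 24, 23 were negative, with a median of -0.10 beside -0.06 over all genes, and Sdha had a log2 fold change of -0.36 (SE 0.14). With all libraries, 0 members of these 5 lists passed over all genes or adjusted over the list alone. Of 21 hypoxia and glycolysis genes, 3 rose and 2 fell with CXCL14 replicate 1 left out, against 4 and 2 adjusted over the list alone. In that fit 2 of 15 circadian clock genes rose, against 7 that rose and 2 that fell adjusted over the list alone, and 2 of 14 glucocorticoid response genes rose, against 3. Of the respiratory chain subunits 1 of 24 fell, and 1 adjusted over the list alone, and 0 of 16 fatty acid and triglyceride synthesis genes passed either way. The medians were then -0.18 for the subunits and 0.16 for the synthesis genes, against 0.09 for the latter with all libraries. Of 19 cholesterol synthesis genes 0 passed with all libraries, and 2 rose without CXCL14 replicate 1, Insig1 with a log2 fold change of 0.75 (limma-trend adjusted p = 0.0302) and Cyp51 with 0.71 (limma-trend adjusted p = 0.0428), while 5 rose and 3 fell adjusted over the list alone. The cholesterol list's median was -0.03 and then -0.07, and that of hypoxia and glycolysis 0.07 and then 0.05.

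Fibroblast markers differed between libraries of the same group. The median FPKM over 14 fibroblast markers was 33.8, 23.4 and 4.85 in untreated replicates 1, 2 and 3 and 29.6, 3.21 and 4.29 in CXCL14 replicates 1, 2 and 3. Their median log2 fold change was -0.94, and the list was not called (camera adjusted p = 0.316). Without CXCL14 replicate 1 it was called down (adjusted p = 0.0363, and adjusted p = 0.804 with an estimated correlation), with a median of -1.96 and 0 of 14 members passing in either fit. For luminal epithelium, cholesterol synthesis and ductal growth factors, camera's direction was up and the mean above 0 while the median was below 0. For matrix remodelling, mast cells, chemokine ligands, chemokine receptors and MHC class II presentation, the direction was up while the median and the mean were below 0. None of these 8 lists was called.

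**Figure D3:**
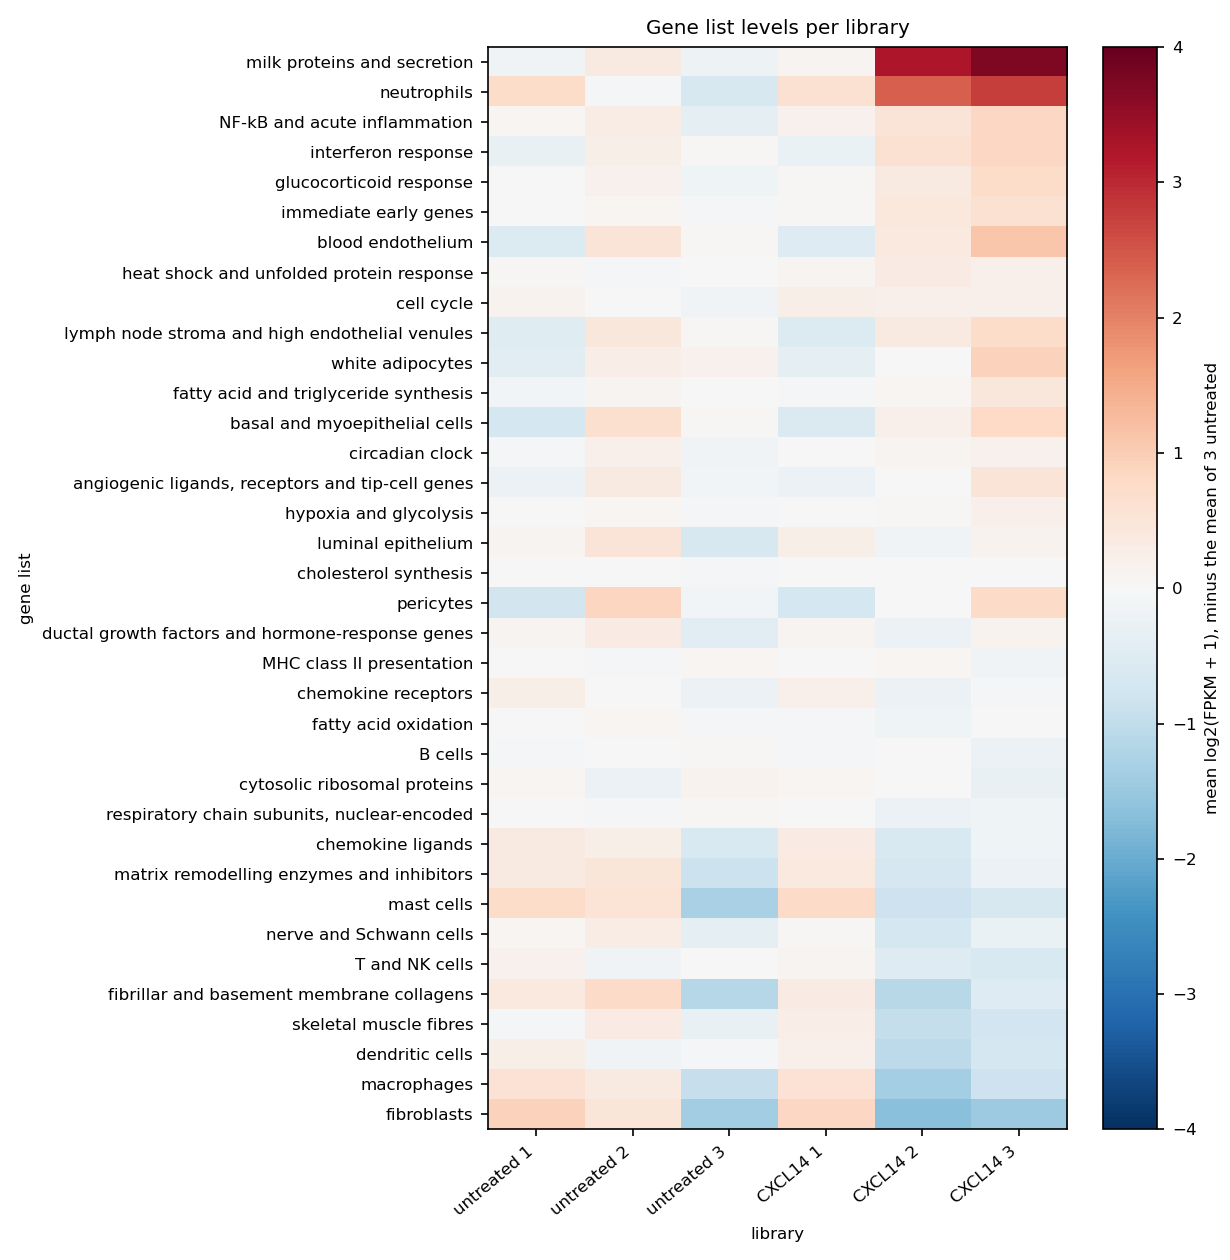
Mean log2(FPKM + 1) over the tested members of each of 36 gene lists (vertical axis) in each library (horizontal axis), as the difference from the mean of the 3 untreated libraries, in colour. The milk list is highest in CXCL14 replicates 2 and 3, and fibroblasts are lowest there and in untreated replicate 3, with median FPKM of 3.21, 4.29 and 4.85.

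Camera called 13 lists higher and 2 lower with all libraries, and 0 of the 15 kept the call with an estimated correlation (smallest adjusted p = 0.520) or with fry (smallest adjusted p = 0.701). Leaving out CXCL14 replicate 3 gave 8 higher and 0 lower, leaving out untreated replicate 1 gave 10 and 0, and leaving out untreated replicate 3 gave 11 and 6. Leaving out CXCL14 replicate 1 gave 14 and 5. In that fit no list was called with an estimated correlation (smallest adjusted p = 0.573), and fry called the milk list alone (adjusted p = 0.0256).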

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

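Leaving out both libraries numbered 1, leaving out CXCL14 replicate 1 together with another choice, a pseudocount of 0.1, quantile normalization and robust variance estimation were added after the data were seen. With all 6 libraries, limma-trend called 0 genes under each scaling, filter, pseudocount, block and variance setting run, and voom called 0, with between 752 and 1133 genes at an unadjusted p under 0.05. Leaving out 1 library gave between 0 and 249 genes higher, between 0 and 348 lower and between 0 and 56 list members called, with calls only without CXCL14 replicate 1. That library left out with median-ratio scaling gave 321 higher, 117 lower and 55 list members, with a pseudocount of 0.1 235, 359 and 52, and with voom 171, 62 and 42. Without both libraries numbered 1, 14 were higher, 1 lower and 7 list members called. Of the genes called in these 4 settings, 366 of 438, 582 of 594, 224 of 233 and 14 of 15 were among the 597 called without CXCL14 replicate 1, in the same direction. All 4 settings share libraries with that fit, so the overlap is no separate check. The log2 fold change of Cxcl14 lay between 0.35 and 1.66 over all settings and passed in none.

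With all 6 libraries, lists called were 0 higher and 0 lower with camera at an estimated correlation and with fry. At the preset correlation, camera gave the following. Lists were between 8 and 16 higher and between 0 and 6 lower with 1 library left out, and 5 lower without both libraries numbered 1. The replicate block gave 0 and 0 genes, 14 lists higher and 6 lower. Deviations from group means correlated at 0.69, -0.30 and 0.06 between libraries of the same number, for numbers 1, 2 and 3. Untreated replicates 2 and 3 correlated best with CXCL14 replicates 3 and 2. This gave no sign of pairing by number beyond number 1. Deviations within a group sum to 0 and so depend on each other, so pairing is not excluded. Of 2917 values of 146 named genes, 2624 kept direction and side of the threshold, 286 newly passed it and 7 turned direction, none of the 7 in a called gene. All 286 came from settings that leave out CXCL14 replicate 1. Part of the 146 genes were named for their calls in such a fit, so their passing there was fixed beforehand. With 1 library left out, the log2 fold change lay between -0.0400 and 0.95 for Tagln, between -0.24 and 0.99 for Cfd, between -0.11 and 0.71 for Fabp4, between -0.0250 and 0.44 for Pnpla2 and between -0.0397 and 0.52 for Adig. The cause was not tested. DESeq2 and the robust edgeR fit, planned for counts, were not run on FPKM, and scaling by library size alone is what FPKM already hold. With between 15245954 and 16983249 recovered reads per library, depth limits genes with few reads, and for the 11516 genes tested the median SD within groups was 0.17 on the log2 scale.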

Other observations

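The tests of the pair of libraries numbered 1, of epithelial and B-cell share, and of the splits for genes with all libraries were chosen after the result was seen.

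Several genes outside the lists were called with CXCL14 replicate 1 left out, and were chosen after their values were seen. Spp1, which encodes osteopontin, rose with a log2 fold change of 5.32 (limma-trend adjusted p = 0.0113), Gdpd3 with 3.27 and Slpi, a protease inhibitor of secretions, with 3.22. Genes that fell had log2 fold changes of -2.43 for Apol7c, -2.19 for Cd209d, -1.85 for H2-M2, -1.77 for Adam23 and -1.65 for Klrd1, a receptor of NK cells. Among the genes of this paragraph, Spp1, Slpi, Gdpd3 and Apol7c also passed without both libraries numbered 1, with limma-trend adjusted p = 0.0475, 0.0102, 0.0475 and 0.0475. That fit used part of the same libraries, so it is no separate check.

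Of 10 skeletal muscle fibre genes, 0 passed with all libraries, over all genes or adjusted over the list alone. Tnni2, a troponin gene, fell over all genes with a log2 fold change of -1.40 when CXCL14 replicate 1 was left out, and 6 fell adjusted over the list alone. In that fit camera called the list down (adjusted p = 0.00912, and adjusted p = 0.573 with an estimated correlation).

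CXCL14 replicate 1 lies closest to untreated replicate 1. A library deposited under both labels would differ by counting noise, a mean chi-square per gene near 1. The value of 2.24 (SE over genes 0.0533) argues against it, as far as sequencing adds counting noise alone. Over genes with under 100 reads in the pair the value was 1.23, nearer to that noise. The SE does not measure differences between sequencing runs. The other same-number pairs lay at 59.6 and 70.4, above the lowest of the pairs with different numbers. That lowest pair holds CXCL14 replicate 1, so it is no like comparison. Untreated replicate 2 with CXCL14 replicate 3 lay at 46.7, and untreated replicate 3 with CXCL14 replicate 2 at 42.0. For numbers 2 and 3 this argues against a batch shared by libraries of the same number. It does not test a batch of number 1 alone. Both libraries coming from the same RNA or tissue sample, with 1 of them then carrying a wrong label, may account for it, since the lowest of the other 14 pairs was at 22.9. A separate treated sample that did not respond and only happens to resemble that untreated sample is argued against only by the few other pairs. Pairs of untreated libraries lay between 23.7 and 42.0, and CXCL14 replicates 2 and 3 at 23.4. Separate samples would be expected at such distances, though the labels do not say which samples came from separate animals. Samples of the same animal could lie closer with both labels right, and this was not tested. Both libraries numbered 1 lay nearer to untreated replicates 2 and 3 (22.9 to 30.7) than to CXCL14 replicates 2 and 3 (48.8 to 84.8). A wrong label on CXCL14 replicate 1 would give this. So would a shared treated sample without a response, so whether a label is wrong, and which, stays undecided.

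CXCL14 replicates 2 and 3 differ from the untreated libraries in milk, neutrophil and T-cell genes. More luminal epithelium as a whole is argued against for the milk genes, since the luminal list had a median log2 change of -0.0709 (SD over members 0.69) against 3.62 for the milk list. That median does not test a gain of secretory cells alone, which stays open. Elf5, of the secretory lineage, was the 1 luminal marker of 17 that rose, with a log2 fold change of 1.68. A lower share of B cells is argued against, since it would raise the other cell types alike, while the T and NK list had a median of -0.63 (SD over members 0.50) and blood endothelium one of 0.65 (SD over members 0.27). Different amounts of lymph node or blood in the samples stay open, with medians of -0.13 for the B-cell list, 0.71 for lymph node stroma and high endothelial venules and 1.13 for red blood cell genes. A response to the treatment and a state of these glands unrelated to it may each account for the difference, and no test separates them. Since the comparison was with untreated samples, a response to CXCL14 itself cannot be told from a response to the way it was given.

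The splits of the samples are too few for a share under 0.05, since 3 against 3 libraries, and 3 against 2, each make 10 splits. For genes called with all libraries the real count is 0, so that 10 of 10 splits give at least as many whatever the data, and this comparison says nothing about chance. The highest other split, untreated replicates 1 and 2 with CXCL14 replicate 1 against the rest, gave 306 genes, which points to a structure of the samples. For lists called by camera, 7 of 10 gave at least the real 15, and the highest other gave 23. For genes called without CXCL14 replicate 1, 1 of 10 gave as many as the real 597, and the highest other gave 156.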
